A study of Zea mays with 16 samples.

How the data were processed

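Leaf RNA of 4 maize lines (B73, B104, CML333 and M37W) was profiled at 26 °C and after chilling at 4 °C, with 2 libraries per line and temperature and 16 libraries in all. Libraries were made with a QuantSeq forward kit, which primes on poly(A) tails and reads the transcript's 3′ end, and were sequenced on an Illumina NextSeq instrument, per the labels' protocols. The length of the chilling treatment, the age of the plants and the leaf sampled are not given in the sources used here.

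The authors deposited 1 table per library, which holds whole-number counts of reads per gene ID and no normalization. Reads were aligned with STAR, and edgeR was used at a later step, per the submitters' processing notes. Their versions, the genome build, the annotation and the treatment of reads with several alignments are not given in the sources used here. For each line the authors also deposited a table with a signal per gene and library that is never negative. Tested against the counts, every value of this signal was the library's count divided by 1 constant per library (100% of values within a relative 1e-06), and the constants, on a CPM scale, stood for 0.887 to 1.136 times the library's total counts. These tables held 17992 gene IDs for B73, 18110 for B104, 17420 for CML333 and 17102 for M37W, the IDs that reached 1 on their own scale in at least 2 of the line's 4 libraries. They add no measurement to the counts and give no comparison, so no test rests on them and no calls were counted in them.

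The count tables list 46430 IDs. Of these, 44146 are nuclear gene models, 1765 are Ensembl noncoding RNA IDs (beginning with ENSRNA), 154 are microRNA IDs, 208 are mitochondrial and 157 are plastid. The files do not pair the nuclear IDs with names, and none of the 44146 matched the RefSeq gene table used for names, while 518 IDs had a symbol, all of them microRNA, mitochondrial or plastid. At most 2 nuclear IDs that rose and 2 that fell are therefore printed, without names. The 33 gene lists fixed for pathways and leaf cell types had tested members in 2 cases only. The list of photosystem subunits had 1 (psaJ), and the list of cytosolic ribosomal proteins had 3 (rps12, rps1 and rps7, all organelle genes and so not cytosolic). No list reached the minimum of 5 tested members, so 0 lists could be tested and none is reported as having moved.

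Groups were taken from the line and temperature in the labels. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups given (17410 IDs), libraries were scaled by the trimmed mean of M-values (TMM), and the factors ran from 0.845 to 1.20. All 16 libraries entered 1 quasi-likelihood fit with a mean for each of the 8 groups (estimateDisp, glmQLFit with robust estimation, glmQLFTest), with no covariate and no fold minimum. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and all tests were two-sided. The contrasts were the chilled minus the control mean in each line, the mean of these 4 responses, any difference among them, each line's response against the mean of the other 3, any difference among the 4 control groups, and each control group against the mean of the other 3. The fold changes are log2 values with standard errors (SE), and levels are CPM, the usual scaling of counts by the library's total. The groups, tests, contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined.

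Named genes had to have a symbol or an informative description. Per line, the 5 highest and 5 lowest log2 fold changes were taken among called genes whose libraries did not overlap between the temperatures and that averaged at least 10 CPM in the higher group. For genes called the same way in all 4 lines, up to 6 in each direction were to be named, or 2 IDs where no names could be had. Up to 2 genes in each direction were to be named per gene list. For each line against the others, up to 3 higher and 3 lower called genes with the smallest p and at least 10 CPM in a group were taken. Zm00001d009022 and Zm00001d024763, which fell in B73 and M37W, were chosen after their values were seen.

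Alternatives were DESeq2 1.42.0, limma 3.58.1 with voom, size factors of DESeq2 within edgeR, no low-count filter, a filter of 1 CPM in 4 libraries (planned as the stricter but keeping 19323 IDs, more than filterByExpr), an adjusted p under 0.01, a fold of at least 2, each library left out in turn, a replicate block by either of the numbers in the labels, and each line's 4 libraries fitted alone. Added after the data were seen were a fit without the B104 and CML333 libraries, the same with a block, nuclear IDs only, the count of genes called the same way in B73 and M37W, and tests of the ID classes with camera and fry of limma. A chilling score was also added. It is the median of log2(CPM + 1) over 867 genes that rose in both B73 and M37W minus that over 355 of the 356 genes that fell in both (for 1 the adjusted p in M37W was 0.05 after rounding, so it was left out). Genes that part 1 line from another were those with at least 10 CPM in every library of 1 and at most 1 CPM in every library of the other. In any library such a gene was on at 5 CPM or more, off at 1 CPM or less, and otherwise left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

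Total counts were 1780344 to 2705564 per library. A count of 0 allows a level of up to 3 counts, which is 1.109 to 1.685 CPM per library. These floors and the intervals given for low counts (95%, exact) cover counting error only, because reads without molecular identifiers are not independent molecules. The steps were tested on simulated counts for the B73 contrast, with 200 changed genes and otherwise 1 mean per gene over all libraries. The shares recovered are therefore not the power of the real contrast, where lines differ and more genes may change. With 16 libraries and 16280 genes tested, 0% of 92 genes changed 2-fold and 7.22% of 97 genes changed 4-fold were recovered, and 2 unchanged genes were called. With the 8 libraries of B73 and M37W and 14457 genes tested, these shares were 16.8% of 95 and 73.7% of 95, with 6 unchanged genes called. The labels do not say that the 2 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of a group agreed within sampling noise, so each library was counted as 1 replicate.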

Results

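The series asked how leaves of 4 maize lines differ in their response to chilling. B73 is the inbred whose genome has served as the maize reference, B104 is an inbred used for transformation, and CML333 and M37W are founders of the nested association mapping population. Plants were kept at 26 °C (control) or chilled at 4 °C, under 14 h of light and 10 h of dark at 250 µmol of photons per square metre and second. Each line had 2 control and 2 chilled libraries of 3′ end reads, and replicates are given in the order 1, 2. Total counts for B73 were 2582414 and 2428008 in the control and 2420903 and 1780344 in the chilled libraries. For B104 they were 2705564 and 2644475 in the control and 2162046 and 2242153 in the chilled libraries. The CML333 libraries held 2286771 and 2236517 counts in the control and 2080691 and 2312146 in the chilled group, and the M37W libraries held 2024851 and 2206293 in the control and 1953922 and 2028974 in the chilled group.

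Replicates correlated across genes at r = 0.948 in the B73 control, 0.952 in the B73 chilled, 0.969 in the M37W control and 0.966 in the M37W chilled group, on log2(CPM + 1). The 2 B104 control libraries stood apart. They correlated with each other at 0.877 and with the other 14 libraries at 0.242 to 0.415, whereas those 14 correlated among themselves at 0.555 to 0.969. The libraries labelled CML333 chilled correlated with each other at only 0.765, the lowest of the 8 groups. Genes are not independent replicates, so these correlations describe the libraries only.

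**Figure D1:**
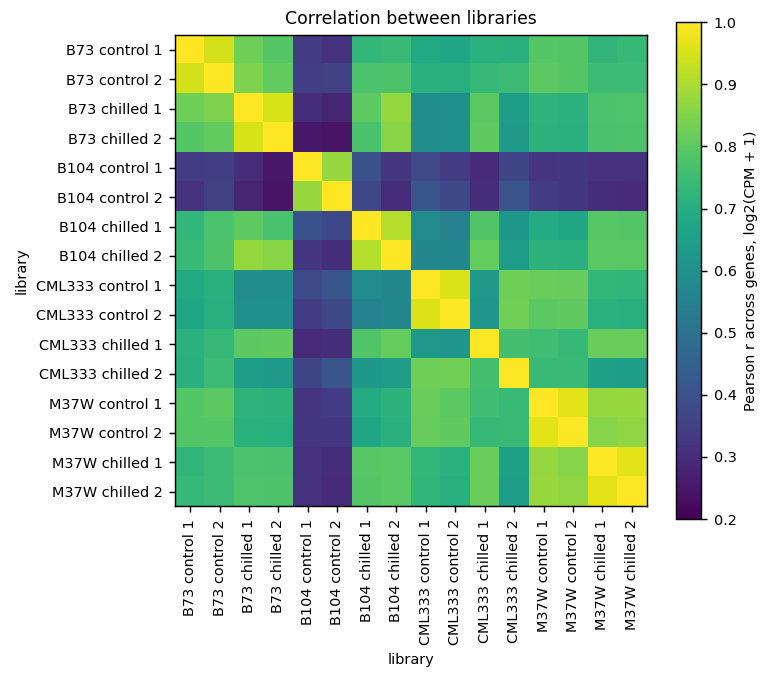
Pearson correlation across genes of log2(CPM + 1) between all 16 libraries, with color running from 0.2 to 1. The 2 B104 control libraries correlated with the other 14 at 0.242 to 0.415, and the chilled pair labelled CML333 at 0.765.

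Chilling of B73 raised Zm00001d032186 from 2.60 ± 0.396 CPM to 81.8 ± 10.6 CPM (SD, n = 2 each) and Zm00001d012292 from 43.4 ± 5.56 to 248.7 ± 9.33 CPM. The plastid gene ycf3 (ZemaCp024), whose product assists the assembly of photosystem I, rose from 15.9 and 26.8 to 210.3 and 353.3 CPM. Zm00001d009022 fell from 33.6 ± 4.46 to 1.40 ± 1.99 CPM, and Zm00001d024763 fell from 76.1 ± 31.0 to 4.44 ± 0.725 CPM. Of 6 plastid IDs tested, ycf3 passed the threshold (2 rose when adjusted over the list alone). Of 22 mitochondrial IDs 0 passed in edgeR's fit of all 16 libraries, 4 had an unadjusted p under 0.05, and DESeq2 called 1 and voom 0. In all, 385 genes rose and 217 fell, 602 of the 17410 tested, and every one of the 602 changed at least 2-fold. The median log2 fold change was 3.42 among those that rose and -2.52 among those that fell.

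In edgeR's quasi-likelihood test of all 16 libraries, the log2 fold change in B73 was 5.23 (SE 0.698, adjusted p 0.00468) for Zm00001d032186, 4.00 (SE 0.816, adjusted p 0.0231) for ycf3 and 2.79 (SE 0.494, adjusted p 0.0132) for Zm00001d012292. It was -4.42 (SE 0.936, adjusted p 0.0262) for Zm00001d009022 and -3.81 (SE 0.589, adjusted p 0.00873) for Zm00001d024763. The calls for ycf3, Zm00001d009022 and Zm00001d012292 were lost when any 1 of the 4 B73 libraries was left out (adjusted p up to 0.227, 0.156 and 0.172), that for Zm00001d024763 without 3 of the 4 (up to 0.0892) and that for Zm00001d032186 without either B73 control (up to 0.0899). Without the B104 and CML333 libraries, whose spread enters the fit of all 16, B73 had 4212 called genes (2396 rose and 1816 fell, of 15174 tested, with 2609 to 4258 called when 1 of the 8 libraries was left out), and the B73 libraries alone gave 3371. In the fit of all 16 the count stayed within 1.5 times when a B104 library was left out, and otherwise ran from 8 without control replicate 2 of B73 to 1991 without chilled CML333 replicate 1. DESeq2 called 1249 genes and limma with voom 927. In the fit without B104 and CML333, the mitochondrial ccmFN fell in B73 (log2 fold change -3.096, SE 0.571, edgeR adjusted p 0.00249). So did the plastid matK (-2.505, SE 0.411, adjusted p 0.00035). Neither passed in the fit of all 16 (adjusted p 0.0881 and 0.164). The B73 libraries alone also called the mitochondrial rrn18 (1.157, edgeR adjusted p 0.0446) and orf99-d (-1.855, adjusted p 0.0463). Both genes missed the threshold in edgeR's fit without B104 and CML333 (adjusted p 0.0504 and 0.0681).

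Chilling of M37W raised Zm00001d032186 from 12.02 ± 6.75 to 186.1 ± 12.8 CPM and Zm00001d012292 from 12.1 ± 0.272 to 123.4 ± 65.8 CPM (SD, n = 2). Zm00001d009022 fell from 123.6 ± 0.861 to 5.52 ± 0.563 CPM, and Zm00001d024763 fell from 32.1 ± 2.74 to 3.51 ± 0.617 CPM. The ycf3 level was 5.93 ± 0.694 CPM in the control and 59.1 ± 10.5 CPM in the chilled libraries, a log2 fold change of 3.37 (SE 0.851) that missed the threshold in edgeR's test of all 16 libraries (adjusted p 0.083). The plastid gene matK, which encodes a maturase for intron splicing, stood at 68.5 ± 9.55 and 23.3 ± 4.00 CPM (adjusted p 0.466). In edgeR's fit of all 16 libraries 0 of the 6 plastid and 0 of the 22 mitochondrial IDs passed, with 2 and 1 at an unadjusted p under 0.05, while DESeq2 called 1 and 0 and voom 0 and 0. Adjusted over the list alone, 1 plastid ID rose. The M37W libraries alone called the mitochondrial orf99-d (log2 fold change 1.454, edgeR adjusted p 0.000824) and rrn18 (1.05, adjusted p 0.0129). They also called the plastid trnK (-1.08, adjusted p 0.0158) and psaJ (-1.921, adjusted p 0.0209). In edgeR's fit of B73 and M37W these genes missed the threshold (adjusted p 0.171, 0.0974, 0.606 and 0.0614).

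All 16 libraries together gave 71 called genes in M37W, of which 42 rose and 29 fell. The log2 fold changes were 4.01 (SE 0.621, adjusted p 0.0231) for Zm00001d032186, 3.41 (SE 0.523, adjusted p 0.0231) for Zm00001d012292, -4.41 (SE 0.790, adjusted p 0.0378) for Zm00001d009022 and -3.12 (SE 0.605, adjusted p 0.0462) for Zm00001d024763. With 1 library left out, the calls for Zm00001d032186 and Zm00001d012292 were lost without any 1 of the 4 M37W libraries (adjusted p up to 0.365 and 0.352), that for Zm00001d009022 in 8 of 16 such fits (up to 0.352) and that for Zm00001d024763 in 10 of 16 (up to 0.366). Without the B104 and CML333 libraries, 2864 genes were called in M37W (1597 rose and 1267 fell, with 1356 to 3519 called when 1 of the 8 libraries was left out) and the M37W libraries alone gave 4218. In that smaller fit ycf3 rose in M37W (log2 fold change 3.36, SE 0.404, edgeR adjusted p 2.9e-05, with 3.39e-08 to 0.536 over all alternatives) and matK fell (-1.504, SE 0.380, adjusted p 0.0113, with 7.69e-05 to 0.824 over all alternatives). In the fit of all 16 the M37W count stayed within 1.5 times only when a chilled B104 library was left out, and otherwise ran from 0 without any 1 of the 4 M37W libraries to 1087 without chilled CML333 replicate 2. Without an M37W library, filterByExpr kept more genes and the lone library was assumed to vary like the other groups. At an unadjusted p under 0.05 there were 2729 genes in M37W, DESeq2 called 612 and limma with voom 173.

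**Figure D2:**
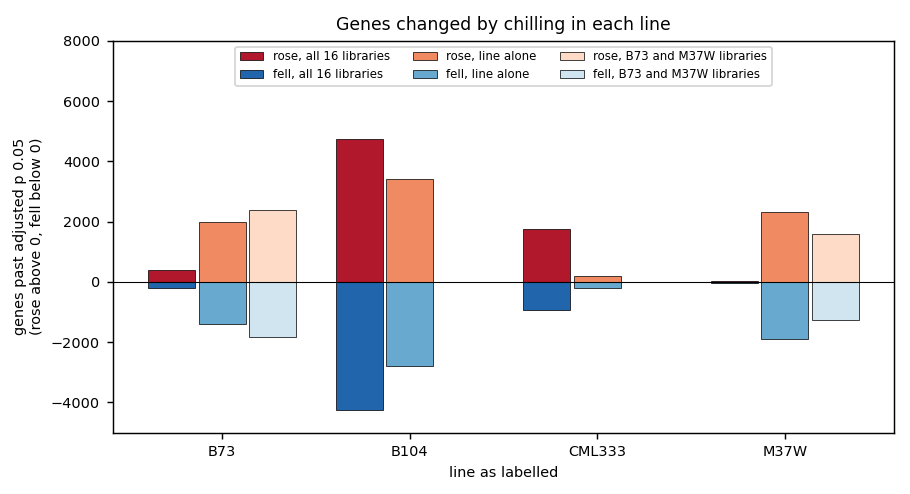
Genes past an adjusted p of 0.05 for chilled against control leaves in each line as labelled, counted upward for genes that rose and downward for genes that fell. Bars of each line come from the fit of all 16 libraries, from the line's own 4 libraries and, for B73 and M37W, from the fit of those 8 libraries, where the M37W count went from 71 to 2864.

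B73 and M37W shared part of their response. In the fit without the B104 and CML333 libraries, 867 genes rose in both lines, where independent lists would share 252, and 356 fell in both, where independent lists would share 152. A further 160 genes rose in B73 and fell in M37W, and 72 did the opposite. The number that independent lists would give was not worked out for these opposite calls. The log2 fold changes of the lines correlated across the 15174 genes at r = 0.409. In the fit of all 16 libraries, 13 genes rose and 6 fell in both (0.929 and 0.361 for independent lists), and each of the 71 genes called there in M37W was also called in the same direction in the smaller fit. The test of the difference between the responses of B73 and M37W called 1536 genes in the same fit. When 1 of the 8 libraries was left out, the 1223 shared genes became 709 to 1345 and the 1536 became 730 to 1885.

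In B104, part of the organelle transcripts differed between the control and the chilled libraries, while as whole classes the plastid IDs missed the threshold in camera (adjusted p 0.099 with a preset and 0.826 with an estimated correlation) and the mitochondrial IDs passed with the preset correlation only (0.0238 and 0.826). Of 6 plastid IDs, 5 rose, among them ycf3, trnK (a lysine transfer RNA) and matK, which lies in the intron of trnK so that reads of the pair cannot be fully told apart. Of 22 mitochondrial IDs, 10 fell, 2 rose and 10 missed the threshold. Only 19 of the 22 pass the low-count filter without the B104 controls, and of these 7 fell and 2 rose. The mitochondrial ribosomal RNA rrn18 fell from 6694 ± 1950 to 92.7 ± 78.2 CPM (SD, n = 2) and nad4, a subunit of respiratory complex I, fell from 825.3 ± 284 to 25.5 ± 20.9 CPM. The B104 control libraries that stood apart hold these differences, since mitochondrial IDs made up 1.36% of their counts on average and 0.105% to 0.321% in the other 7 groups. Their ENSRNA IDs made up 5.03% and 3.69% of counts, against at most 0.101% in any other library, and 208 of 236 such IDs fell on chilling while 1 rose. Without the B104 controls the low-count filter keeps 71 of the 236, of which 46 fell in B104 and 1 rose.

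In edgeR's test the log2 fold changes in B104 were -6.15 (SE 1.11, adjusted p 0.00055) for rrn18, -5.00 (SE 1.14, adjusted p 0.0027) for nad4 and -3.28 (SE 0.737, adjusted p 0.00234) for atp4, a subunit of mitochondrial ATP synthase. The serine transfer RNA trnS-a fell by 5.18 on the log2 scale (SE 0.887, adjusted p 0.000358), and trnS-b fell from 66 counts over the control group to 1 over the chilled group, a CPM ratio of 54.3 (95% interval 9.42 to 2180, edgeR adjusted p 0.00325). The ratio for ycf3 was 193 (95% interval 53 to 1600) from 318 counts in the chilled and 2 in the control group (adjusted p 0.000195). The log2 fold change was 4.47 (SE 1.41, adjusted p 0.0167) for trnK and 3.96 (SE 1.12, adjusted p 0.00925) for matK. With 0 control counts over the group, psaJ (a photosystem I subunit) was at least 4.05-fold and petD (a cytochrome b6f subunit) at least 11.3-fold higher in the chilled group, against a floor of 3 counts over the group. Organelle reads can be shared with nuclear copies of organelle DNA, and how such reads were counted is not given in the sources used here. The kit primes on poly(A) tails, so organelle values in every line count only RNA that was primed this way. Whether that part of the organelle RNA was the same in all libraries was not tested.

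B104 had 9019 called genes, 4754 that rose and 4265 that fell, and its 4 libraries alone gave 6204. Zm00001d032186 (log2 fold change 3.90, SE 0.652, edgeR adjusted p 0.000308) and Zm00001d012292 (1.498, SE 0.469, adjusted p 0.0159) rose in B104 as in B73. Zm00001d024763, by contrast, rose from 0.748 ± 0.0121 to 26.1 ± 19.9 CPM (log2 fold change 5.09, SE 0.720, adjusted p 8.72e-05). Its control level comes from the B104 libraries that stood apart. The count of 9019 rests on control libraries in which the 50 most abundant nuclear genes of the other 6 control libraries took 4.72% and 5.95% of counts, against 14.9% to 21.9% in those 6. The call for trnK was lost without chilled replicate 1, control replicate 1 or control replicate 2 of B104, that for matK without chilled replicate 1 or control replicate 2, and that for Zm00001d012292 without chilled or control replicate 1, with adjusted p up to 0.224.

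**Figure D3:**
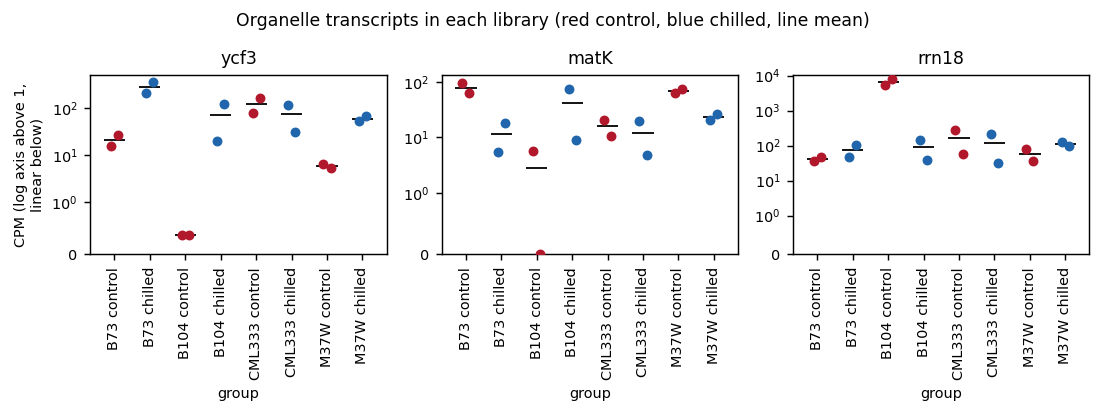
Levels of the plastid transcripts ycf3 and matK and the mitochondrial ribosomal RNA rrn18 in each library, as CPM on an axis that is logarithmic above 1 and linear below, with points for libraries and lines for group means. The B104 controls held 6694 CPM of rrn18 on average and the other 7 groups 40.7 to 165.5 CPM, while ycf3 stood at 0.374 CPM in the B104 controls.

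In the libraries labelled CML333, Zm00001d032186 rose from 7.06 ± 2.39 to 93.0 ± 39.8 CPM and Zm00001d012292 from 2.65 ± 0.584 to 36.5 ± 20.4 CPM (SD, n = 2). Zm00001d024763 rose too, from 2.86 ± 1.52 to 52.6 ± 12 CPM, whereas it fell in B73 and M37W. That rise rests on control libraries whose line label is left open further on. For ycf3 the level was 119.9 ± 60 CPM in the control and 73.3 ± 60.8 CPM in the chilled libraries, a difference within the spread of the replicates (log2 fold change -0.45, SE 0.723, edgeR adjusted p 0.747). In edgeR 0 of 22 mitochondrial and 0 of 6 plastid IDs passed, with 4 and 0 at an unadjusted p under 0.05, while DESeq2 called 2 and 0 and voom 1 and 0. A total of 1743 genes rose and 934 fell, 2677 in all.

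The edgeR log2 fold changes were 3.96 (SE 0.634, adjusted p 0.00147) for Zm00001d032186, 4.01 (SE 0.587, adjusted p 0.000836) for Zm00001d012292 and 4.41 (SE 0.617, adjusted p 0.000597) for Zm00001d024763. Chilled replicate 2 had a chilling score of -2.39, within the range of the 8 control libraries (-2.40 to -0.61), while the other 7 chilled libraries scored 1.38 to 1.97. Over 81 genes that were on in B73 and off in chilled B104 or the reverse, control and chilled libraries labelled CML333 shared 76.4% of on or off states, against 97.8% for control and chilled M37W. The line's 4 libraries alone gave 387 genes. The count of 2677 became 1283 without chilled replicate 1, 739 without control replicate 1 and 684 without control replicate 2 of CML333, and 3793 without chilled replicate 2.

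**Figure D4:**
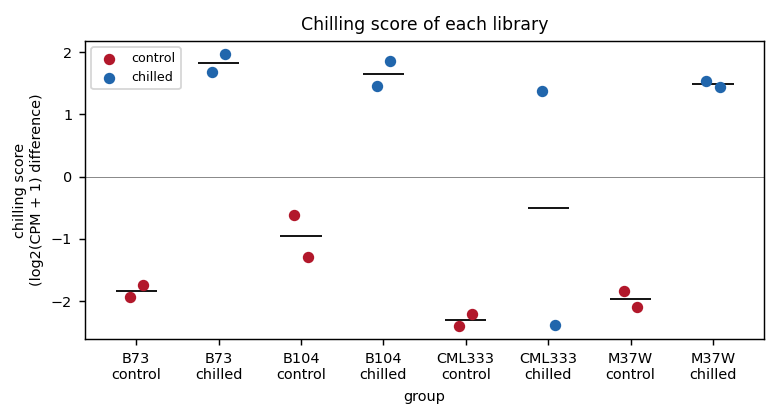
Chilling score of each library, the median log2(CPM + 1) of 867 genes that rose minus that of 355 of the 356 genes that fell in both B73 and M37W, with points for libraries and lines for group means. Chilled CML333 replicate 2 lies at -2.39 among the controls, and the genes were chosen on the B73 and M37W libraries, so their separation is no independent result.

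Over all 4 lines, 4 genes rose in each line and 0 fell in each, where independent lists would share 0.0254 and 0.00475. Zm00001d032186 and Zm00001d012292 were among the 4, and the files do not pair IDs with names. The test of the mean response called 6421 genes, of which 3903 rose and 2518 fell. In that test ycf3 rose (log2 fold change 3.59, SE 0.452, edgeR adjusted p 0.000114), as did Zm00001d032186 (4.28, SE 0.326, adjusted p 1.42e-05) and Zm00001d012292 (2.93, SE 0.260, adjusted p 2.4e-05). The mitochondrial genes nad4 (-1.86, SE 0.508, adjusted p 0.0115), ccmFN (-1.82, SE 0.447, adjusted p 0.00632), which serves cytochrome c maturation, and atp4 (-1.45, SE 0.436, adjusted p 0.0186) fell. Of 22 mitochondrial IDs in that test, 4 fell, 1 rose and 17 missed the threshold.

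For ycf3 the mean joined 4.00 in B73, 3.37 in M37W, -0.45 in CML333 (adjusted p 0.0231, 0.083 and 0.747) and the rise in B104, which rests on 2 control counts. For nad4 it joined log2 fold changes of -5.00 in B104, whose controls stood apart, and -2.12 in CML333 with 0.16 in B73 and -0.48 in M37W (edgeR adjusted p 0.0027, 0.181, 0.964 and 0.883). For atp4 it joined -3.28 in B104 with -1.11 in B73, -0.69 in CML333 and -0.71 in M37W (adjusted p 0.00234, 0.446, 0.747 and 0.7). For ccmFN it joined -3.055 in B73, -2.33 in CML333, -1.33 in B104 and -0.56 in M37W, none past the threshold (adjusted p 0.0881, 0.114, 0.208 and 0.805). The count of genes changed the same way in all 4 lines stayed within 1.5 times only when a B104 library was left out, and otherwise ran from 0 without a control library of B73 or any library of M37W to 292 (281 rose and 11 fell) without chilled CML333 replicate 2. DESeq2 gave 70 genes that rose and 1 that fell in all 4, and voom 6 and 0. In edgeR's fit of all 16 libraries 0 genes fell in all 4 lines, although 10243 genes were called in at least 1 line and 3771, 10067, 5064 and 2729 genes had an unadjusted p under 0.05 in B73, B104, CML333 and M37W.

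The lines responded differently at 6148 genes by edgeR's test of any difference among the 4 responses. Among named genes Zm00001d024763 (adjusted p 2.92e-05), Zm00001d009022 (0.00383), ycf3 (0.00387), rrn18 (0.0045) and matK (0.0184) differed. B104 had the most, with 5902 against the mean of the other 3 lines, where rrn18 responded lower by a log2 difference of -6.83 (SE 1.21, adjusted p 0.000782) and matK higher by 5.32 (SE 1.25, adjusted p 0.00519). The response of ycf3 was higher in B104 (adjusted p 0.00685) and lower in CML333 (adjusted p 0.00378), both resting partly on the 2 counts of ycf3 in the B104 controls. For nad4 the B104 response was lower, by a log2 difference of -4.18 (SE 1.21, adjusted p 0.0163), as it was for trnS-a (adjusted p 0.0215), and for petD, at 0 counts in the B104 controls, it was higher (adjusted p 0.0249). Of the B104 calls against the others, trnS-a was lost in 4 of 16 fits with 1 library left out (adjusted p up to 1), petD in 3 (up to 0.119), nad4 and ycf3 in 2 each (up to 0.113 and 0.0651) and matK in 1 (0.0812). Against the mean of the others, 1936 genes differed in CML333, 851 in B73 and 1105 in M37W. In each of these counts the mean of the others contains the B104 response, with its controls that stood apart. For B73 and M37W it also contains the response of the libraries labelled CML333. The counts are therefore not of responses particular to the line.

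The count for B104 holds the control libraries that stood apart, and without the B104 and CML333 libraries 1536 genes differed between B73 and M37W (730 to 1885 with 1 library left out). The B73 count stayed within 1.5 times without a B104 library or a CML333 control and otherwise ran from 121 (without chilled B73 replicate 2) to 1877 (without chilled CML333 replicate 2), the CML333 count became 867 and 751 without its controls and 1261 without M37W control replicate 1, and the M37W count ran from 2 without either chilled M37W library to 2102 without chilled CML333 replicate 2.

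At 26 °C the 4 lines differed at 10971 genes. B104 stood out with higher rrn18 (log2 difference 6.84 from the mean of the other lines, SE 0.710, edgeR adjusted p 3.59e-06), trnS-a (adjusted p 1.66e-06) and trnS-b (adjusted p 4.52e-05), and lower ycf3 (at 0.374 CPM, adjusted p 0.000737), psaJ (at 0 counts, adjusted p 0.0039) and matK (-3.72, SE 1.03, adjusted p 0.00714). In the libraries labelled CML333, ycf3 (at 119.9 CPM, adjusted p 0.000234), trnK (3.55, SE 0.838, adjusted p 0.00866) and the mitochondrial reading frame orf101-a (3.23, SE 0.726, adjusted p 0.00647) were higher, and atp4 (-3.09, SE 0.747, adjusted p 0.00942) and orf99-d (-2.71, SE 0.742, adjusted p 0.0178) were lower. The mean of the others contains the B104 controls, which differed in the opposite direction. Their log2 differences were -5.60 for ycf3, -4.31 for trnK, -2.83 for orf101-a, 3.295 for atp4 and 1.94 for orf99-d. The CML333 controls held 4 and 2 counts of atp4. M37W had higher psaJ, at 17.1 ± 13.7 CPM where B73 had 2.19, CML333 4.64 and B104 0 (adjusted p 0.00186), and higher ccmFN (2.22, SE 0.621, adjusted p 0.0213), with ccmFN at 333.7 ± 141 CPM against 50.4 to 103.3 CPM in the other 3 control groups. B73 had higher orf99-d, at 2498 ± 553 CPM (2.27, SE 0.567, adjusted p 0.00918), and lower nad4 (-3.16, SE 0.974, adjusted p 0.0287) and orf140-b (-2.46, SE 0.789, adjusted p 0.0341). Both B73 and M37W had higher matK (adjusted p 0.0302 and 0.0362) and lower rrn18 (adjusted p 0.0133 and 0.0455) than the mean of the others, which contains the B104 controls, where nad4 and orf140-b were high too (3.91 and 2.40). In 16 fits with 1 library left out, the call was lost in 5 each for nad4 and orf140-b in B73 and ccmFN in M37W, in 6 and 9 for matK and 2 and 11 for rrn18 in B73 and M37W, and in 2 each for atp4 and orf99-d in CML333 (adjusted p up to 0.318). It was lost in 1 each for orf99-d in B73, trnK and orf101-a in CML333, psaJ in M37W and matK in B104 (up to 0.29).

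By line, 9689 genes of B104, 4482 of B73, 4134 of CML333 and 3739 of M37W differed from the mean of the other 3 control groups, and B73 and M37W alone differed at 4515 genes in the fit without B104 and CML333 (2627 to 4816 with 1 library left out). Leaving out a line's own control libraries lowered its count to 2197 and 2591 for B73, 1874 and 1414 for CML333 and 1606 and 1475 for M37W. Differences between lines can include reads of 1 line that align less well to a shared reference, which was not tested here. Between single lines, B73 and B104 differed at 8530 genes in the control and 852 in the chilled libraries, whereas B73 and M37W differed at 1650 and 1924.

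**Figure D5:**
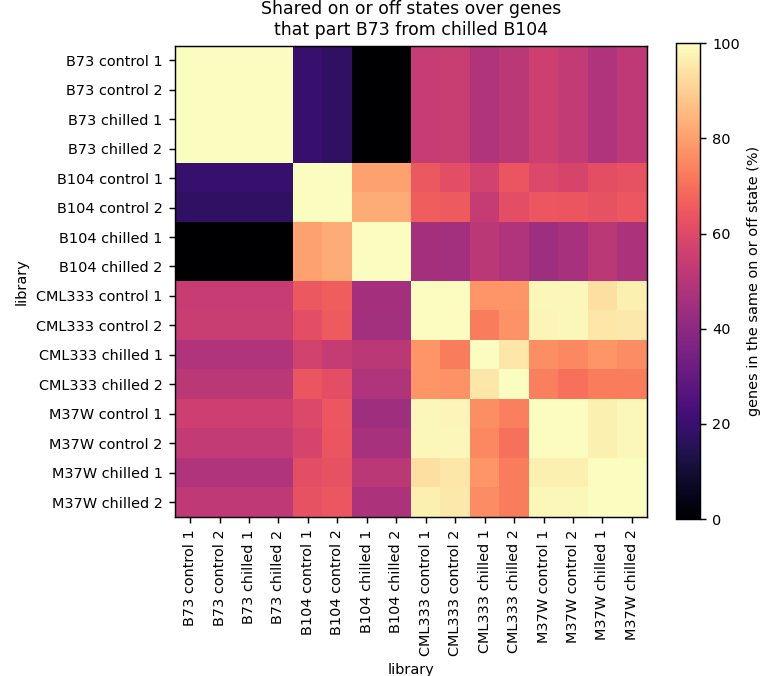
Share of genes in the same on or off state for each pair of the 16 libraries, in percent, over 81 genes that are on in B73 and off in chilled B104 or the reverse, so that the values among B73 and chilled B104 are set by that choice. Control libraries labelled CML333 shared 98.5% of states with the M37W controls and 76.4% with the chilled libraries labelled CML333.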

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

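The tests of a difference between lines were planned, whereas the count of other splits and every test of the libraries in this part were chosen only after the results were seen. The lines differed in their response to chilling at 6148 genes, and against the mean of the other lines at 5902 genes in B104, 1936 in CML333, 1105 in M37W and 851 in B73 (edgeR, adjusted p under 0.05). Except in the count for B104, the mean of the other lines contains the B104 response, which rests on controls that stand apart. Among named genes, the test of a difference in response gave an adjusted p of 2.92e-05 for Zm00001d024763, which rose in B104 and CML333 and fell in B73 and M37W. Both rises rest on low levels in doubted controls. These are the B104 controls that stand apart (0.739 and 0.756 CPM) and the CML333 controls, whose line label is open (3.94 and 1.79 CPM). The test gave 0.00383 for Zm00001d009022, which fell in B73 and M37W with a log2 fold change of 2.21 in B104 (adjusted p 0.0928). It gave 0.00387 for ycf3, which rose in B73 and B104 and had a log2 fold change of -0.45 in CML333. It gave 0.0045 for rrn18 and 0.048 for nad4. In the fit of all 16 libraries both passed the threshold in B104 only, where they were high at control temperature. Fitted alone, B73 and M37W each had a rise of rrn18 (1.157 and 1.05, edgeR adjusted p 0.0446 and 0.0129). In edgeR's fit of the libraries of both lines, rrn18 missed the threshold in each (adjusted p 0.0504 and 0.0974). The test of a difference gave 0.0184 for matK, which rose in B104. Without the B104 and CML333 libraries, matK fell in B73 (-2.505) and M37W (-1.504, edgeR adjusted p 0.00035 and 0.0113). The same test gave 0.0332 for orf140-b, which fell by 3.08 on the log2 scale in B104. For the mean response over the lines, 1 of 60 drawn splits of the libraries within lines, the real split, gave as many as 6421 genes. The highest of the others gave 2980, in a split that kept 3 lines as labelled, and the median was 0. Other splits put differences between the labelled groups, such as that of the B104 controls, into the spread, which lowers their counts. The splits therefore cannot tell a response to chilling from a fault shared by the libraries of a group.

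The 2 B104 control libraries stand apart from the other 14, with r of 0.242 to 0.415 to them. A wrong line label is argued against for M37W by the genes that part it from chilled B104, on which these controls shared 80.8% of on or off states with chilled B104 and 19.2% with M37W controls, and for B73 by those that part B73 from chilled B104, with 18.3% shared with B73 and 81.7% with chilled B104. Loss of RNA by breakdown is not settled by the 83 nuclear genes at 10 CPM or more in both and at most 1 CPM in all other libraries. CPM are shares of a library's total, so an uneven loss can raise the share of what remains. Another tissue makeup or stage at harvest could not be tested, since 0 of the cell type lists had 5 tested members, and it cannot be told apart from a change of temperature in this design because both B104 controls share it. What stays open is that other tissue or stage, RNA quality or library preparation, a line not in this series and a real B104 response. For the line, 80.8% lies below the 97.8% that control and chilled M37W shared on another set of such genes. An exchange of labels with CML333 was not tested. On the genes that part B73 from chilled B104, the B104 controls shared 64.6% with the CML333 controls and 58.8% with chilled CML333.

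The libraries labelled CML333 differ between the temperatures in genes that are on or off by line, sharing 76.4% of states where M37W, not used to choose the genes, shared 97.8%. That temperature switches these genes in every line is argued against by M37W, while a switch in CML333 alone stays open, since chilled replicate 2, which shared 77.6% with the controls and 95.1% with chilled replicate 1, is 1 library that was perhaps not chilled. That CML333 and M37W are alike at both temperatures with all labels right is argued against by the chilled libraries, which shared 73.8% with the M37W controls, while the CML333 controls shared 98.5%. A wrong line label on the control or the chilled libraries stays open as a candidate explanation, as does a biological one by line, and 0 genes at 20 CPM or more in the CML333 controls had 0 counts in the M37W controls (8 the reverse), against 18 at 0 in chilled CML333 (6 the reverse) and 1 and 2 within M37W. In the CML333 controls, 35 genes at 20 CPM or more in chilled M37W had 0 counts (0 the reverse). In the M37W controls, 2 did (1 the reverse). Other values go both ways, since 1301 genes were called between the CML333 and M37W controls, whose r of 0.798 to 0.817 lies below the 0.855 to 0.878 of control with chilled M37W, while CML333 controls had 0.630 and 0.620 with chilled replicate 1 and 0.822 to 0.829 with chilled replicate 2.

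Chilled CML333 replicate 2 had a chilling score of -2.39, where the other 7 chilled libraries scored 1.38 to 1.97. A weaker response of the whole line is argued against by chilled replicate 1, at 1.38. A swap with a control library of the same line is argued against by the controls, the higher of which scored -2.21. A single wrong temperature label or a plant that was not chilled may account for the value, since it lies within the range of the 8 controls (-2.40 to -0.61). They stay open, since 3 of the named genes, chosen with this library in the fit, stood above the CML333 controls in it (Zm00001d032186 at 64.9 CPM against 8.75 and 5.37, Zm00001d012292 at 22.1 against 3.06 and 2.24, Zm00001d024763 at 44.1 against 3.94 and 1.79), and a partial or slower response of that plant was not tested. Zm00001d009022 went the other way. It stood at 57.1 CPM in chilled replicate 2, near the controls (73.5 and 81.8), and at 7.69 CPM in chilled replicate 1. Zm00001d024763 fell on chilling in B73 and M37W, so its higher level is no clear sign of chilling. A wrong line label on the controls compared here also stays open.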

How the results depend on the processing

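The fits without the B104 and CML333 libraries, with nuclear IDs only and of the genes shared by B73 and M37W were chosen only after the results were seen, and the other alternatives were planned. Counts are given as genes called, and a count is called moved where it changed by over 1.5 times. Size factors of DESeq2 in edgeR and nuclear IDs only moved 0 of 17 counts. At an adjusted p under 0.01 there were 51 genes in B73, 980 in CML333, 1 in M37W, 3826 in the mean response, 3149 that differed in response, 183, 3560, 662 and 229 for the response of B73, B104, CML333 and M37W against the others, 2520, 1930 and 1906 for B73, CML333 and M37W against the others at control temperature, and 0 shared by all 4 lines or by B73 and M37W. A fold of at least 2 moved only the mean response, to 4243. DESeq2 gave 1249 in B73, 612 in M37W, 1449 and 1674 for the responses of B73 and M37W against the others, 71 shared by all 4 lines and 210 by B73 and M37W. limma with voom gave 927 in B73, 173 in M37W and 54 shared by both. With no low-count filter (28431 genes) there were 1992 in B73, 1275 in M37W, 1869 and 2015 for their responses against the others, 283 shared by all 4 lines and 527 by B73 and M37W, and a filter of 1 CPM in 4 libraries, planned as stricter but looser here (19323 genes), moved only the last, to 32. No low-count filter that keeps fewer genes was run on all 16 libraries. The cause was not tested for these settings.

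Deviations from the group means of libraries with the same number in the titles correlated at -0.0403 in B73, 0.0289 in B104, 0.105 in CML333 and 0.0909 in M37W. Over all pairs of groups they correlated at -0.15 to 0.257. These values show no strong effect shared by the title number, but cannot decide whether the libraries were paired by design. A replicate block by that number gave 113 genes in M37W, 7 shared by all 4 lines and 29 by B73 and M37W, and moved no other of the 17 counts. A block by the library number in the descriptions gave 180 in B73, 1331 in CML333, and 506 and 1270 for their responses against the others (mean correlation 0.0294 for the same and -0.0145 for other numbers). Without the B104 and CML333 libraries there were 4212 genes in B73, 2864 in M37W, 1536 that differed in response, 4515 at control temperature and 1223 shared by B73 and M37W. The same with the replicate block gave 3920, 2627, 1334, 4207 and 1116, and 4141 for the mean response. The lines alone gave 3371 in B73, 387 in CML333 and 4218 in M37W, with 1214 shared by B73 and M37W. The biological coefficient of variation was 0.371 with all 16 libraries, 0.208 in the 8 of B73 and M37W, 0.452 in B104 and 0.431 in CML333 alone, so the shared spread lowers the calls of B73 and M37W by construction.

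With each library left out in turn, the counts ran from 8 to 1991 in B73, 6551 to 10124 in B104, 684 to 3793 in CML333, 0 to 1087 in M37W, 5330 to 7304 for the mean response, 0 to 292 for all 4 lines, 0 to 499 for B73 and M37W, and 4462 to 7353 for a difference in response. The responses against the others ran from 121 to 1877 in B73, 4249 to 6746 in B104, 751 to 2523 in CML333 and 2 to 2102 in M37W. At control temperature they ran from 9826 to 12626 for any difference, 2197 to 5514 in B73, 8741 to 10916 in B104, 1414 to 5389 in CML333 and 1475 to 4673 in M37W. Of 1454 values of named genes under an alternative, 1294 kept their direction and side of the threshold, 141 lost the call, 16 gained one and 3 reversed. The 3 were the log2 fold change of ycf3 in CML333, never past the threshold, which was 0.01 with the block by library number and ran from -1.86 without chilled replicate 1 to 0.19 without chilled replicate 2 and 0.16 without control replicate 2 of CML333 (edgeR adjusted p 0.207 to 1, the cause was not tested). The depth of 1780344 to 2705564 counts limits genes near 1 CPM, so psaJ, petD and trnS-b are read by their counts. No gene list was tested, and no alternative of one was run.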

Other observations

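The tests of ID classes and of shared genes in this part were chosen only after the results were seen. Genes that rose in both B73 and M37W were mostly higher in the chilled libraries of the other lines too, whereas genes that fell in both showed no such majority in B104 and a small one in CML333. Of the 867 that rose, 748 (86.3%) were higher in chilled B104, with 577 called and 38 called in the opposite direction, and 760 (87.7%) were higher in the chilled libraries labelled CML333, with 370 called and 16 opposite. Of 355 of the 356 genes that fell (1 was left out at an adjusted p of 0.05 after rounding), 173 (48.7%) were lower in chilled B104, with 87 called and 124 opposite, and 201 (56.6%) were lower in CML333, with 33 called and 34 opposite. Among 16188 other genes, 47.2% were higher and 51.8% lower in chilled B104, and 50.8% were higher and 47.2% lower in CML333. The median log2 fold change of the 867 was 3.26 in B104 and 2.55 in CML333, and that of the 355 was 0.05 and -0.15. Both lines hold libraries that stand apart or whose labels are doubted, and the chilled CML333 libraries differed, with 75.5% of the 355 genes lower than the control mean in replicate 1 and 47.6% in replicate 2, and 88.1% and 46.7% of the 867 higher.

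Of 236 tested ENSRNA IDs, 208 fell and 1 rose in B104, but 165 of the 236 passed the low-count filter only through the B104 controls, which stand apart, so a test of the class as a whole decides nothing. Of the 71 that pass without them, 46 fell and 1 rose in B104 (median log2 fold change -3.57), where the fall still rests on those controls. The mean response of the 71 (24 fell, 2 rose, median -1.10) holds that fall, with medians of 0.50 in B73, -0.55 in CML333 and 0.54 in M37W. By limma's camera, the mitochondrial class fell against other genes in B104 with a preset correlation (adjusted p 0.0238, with 3 of 22 IDs passing the filter only through the B104 controls), a call that was lost with an estimated correlation (adjusted p = 0.826). The plastid class, 5 of whose 6 tested IDs rose in B104, had an adjusted p of 0.099 with the preset and 0.826 with the estimated correlation, while fry, which tests whether a set moves 1 way and not against other genes, gave an unadjusted p of 0.00433. Of the 71 ENSRNA IDs, 6 rose and 0 fell in B73, 2 rose and 6 fell in the libraries labelled CML333, and 0 were called in M37W.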
